A study of Mus musculus with 6 samples.

How the data were processed

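The series holds 6 RNA-seq libraries from hearts of mice aged 3 to 6 months, 3 labelled WT and 3 labelled DKO. Per the labels, total RNA was taken from heart tissue, and libraries were strand-specific and paired-end (2 reads of 75 bases, NextSeq 500). The authors deposited 1 table of TPM values, 1 value per gene and library, over 24525 gene rows. Per the submitters' processing notes, bcl2fastq and kallisto 0.44.0 were used with the mm10 build; the annotation and how transcripts were combined into genes are not given in the sources used here. Replicates were not pooled in the deposited TPM table. Of its symbols, 24422 matched the RefSeq gene table of GRCm38, from which positions were taken. In 791 rows a further symbol column differs from the row name, and the row name was used. TPM divides by transcript length and by each library's total, so a change in a few abundant RNAs shifts all other values, and short RNA rows, many inside host genes, get large and unsteady values. Reads shared by near-identical genes, such as histone and globin copies, are split by estimate. TPM keeps no counts, so depth is unknown and no interval from counting is given.

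Groups follow the titles and source names. Replicate 7 is DKO in both but WT in its genotype tag; it was placed in DKO and the other placement was tried. Nothing in the labels says that libraries come from separate animals, so p-values measure only the spread between these libraries. Sex-linked and beta-globin rows differ among DKO 7, 8 and 9 and between WT 4 and the other WT libraries, so these are not repeats of 1 RNA; for WT 5 and WT 6 the spread may be technical. Genes with at least 1 TPM in at least 3 libraries were tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(TPM + 1), with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. This scale understates the change of genes at low TPM. Gene lists, tests, naming rule and first set of alternatives were fixed before the data were examined. Of 34 lists, 33 had at least 5 tested genes and were tested with camera (limma, preset inter-gene correlation 0.01), BH adjusted over the lists, and again with an estimated correlation. Counts per list are given over all genes and adjusted over the list alone.

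Named genes are Mbnl1, Mbnl2 and Mbnl3, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap (without predicted genes and pseudogenes), and the 4 genes with the smallest p of each list. The genes Nppa, Nppb, Gja1, Arntl, Dbp, Ryr2, Atp2a2, Tnnt2, Tnni3, Clcn1, Hcn4, Myl7 and Trim12a, and in the closing part Rpl3, Rpl3l and members of the lists named there, were also or only chosen after their values were seen. Some genes that the naming rule or a later choice gave are not reported here. The planned test of transcript shares could not be run, since the deposited table gives TPM per gene. Alternatives were pseudocount 0.1, no filter, a filter of 5 TPM, median-ratio and quantile scaling, rescaling without haemoglobin and ribosomal RNA, eBayes without trend, array weights, replicate 7 as WT, each library left out, camera with an estimated correlation and fry. A term for sex-linked transcripts, the libraries with Y-linked transcripts alone, and rescaling without structural, short RNA and haemoglobin rows were added after seeing the data.

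The fits were tested on simulated data with 14541 genes, 200 of them changed, for the comparison of DKO with WT. Of genes changed 2-fold on the log2(TPM + 1) scale 42% were recovered, and of genes changed 1.5-fold 13%. Of 57 calls 2 were false, and 0 genes were called when none was changed. Far fewer genes were changed than the 1560 called in the data, which makes the BH threshold stricter. These shares therefore do not give the recovery in the data. A simulated shift of 1 list by -0.5 was called, with 0 other lists. The simulated noise was independent between genes, so this does not test list calls where genes vary together. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.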

Results

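RNA from mouse heart tissue was profiled in 6 libraries, 3 labelled wild type (WT; replicates 4, 5 and 6) and 3 labelled double knockout (DKO; replicates 7, 8 and 9). Per the labels, the DKO animals carried constitutive null alleles of Mbnl1 and conditional alleles of Mbnl2 targeted by Cre recombinase under the Myh6 promoter, which is active in cardiomyocytes. MBNL proteins are RNA-binding regulators of alternative splicing, and their sequestration by expanded CUG repeats is a central feature of myotonic dystrophy. The comparison asks which transcripts differ in the heart when both genes are targeted. Expression was given as TPM, a transcript abundance scaled by transcript length and library total, per gene, with totals between 999963 and 999991 in the 6 libraries, and from 14084 to 14623 genes at 1 TPM or more. TPM keeps no sequencing depth, so the depth behind each value is unknown. Values are mean ± SD of n = 3 libraries per group unless stated, log2 differences are DKO minus WT on the log2(TPM + 1) scale, and coordinates are on GRCm38 (mm10).

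Mbnl1 (chromosome 3, 60472559 to 60629750) was lower in each library labelled DKO, with 102, 108 and 108 TPM in replicates 7, 8 and 9 against 161, 160 and 145 TPM in WT replicates 4, 5 and 6. The log2 difference was -0.55 (SE 0.07; limma, BH adjusted p = 0.00673), and DKO had 0.683 of the WT mean. Mbnl2 (chromosome 14, 120275652 to 120431698) was higher in each library labelled DKO, with 227, 240 and 245 TPM against 189, 168 and 149 TPM, a log2 difference of 0.49 (SE 0.09; limma, BH adjusted p = 0.0232). Mbnl3 (chromosome X, 51113494 to 51205990) lay between 0.267 and 1.26 TPM in all 6 libraries and did not reach the expression filter. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for Mbnl1, 0.1 for Mbnl2 and 0.3 for Mbnl3, where 0.1 is the smallest value the design allows. The rise of Mbnl2 goes against the loss that the genotype names. A gene-level sum includes reads from transcript parts outside a deletion and, for Mbnl2, from cells without Cre. Neither value therefore checks the deletion, and directions below rest on libraries labelled DKO. The Mbnl2 call was lost without WT replicate 5 (limma, BH adjusted p = 0.0638), WT 6 (0.0548), DKO 7 (0.0548), DKO 8 (0.0777) or DKO 9 (0.0704), while Mbnl1 stayed called in each of these fits. DKO replicate 7 is DKO in its title and source name but WT in its genotype tag. Counted as WT, it left Mbnl1 at -0.37 (limma, BH adjusted p = 0.529) and Mbnl2 at 0.42 (limma, BH adjusted p = 0.501).

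**Figure D1:**
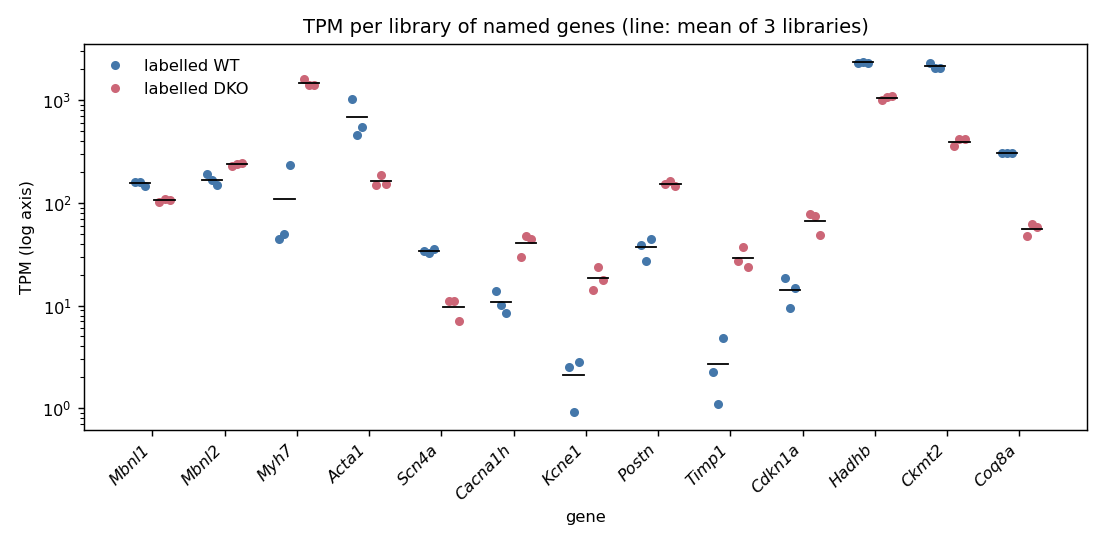
TPM of 13 genes in each library on a log axis, with WT libraries in blue, libraries labelled DKO in red and the mean of 3 libraries as a line. Mbnl1 lies between 102 and 108 TPM in DKO and between 145 and 161 TPM in WT, while Myh7 averages 1469 TPM in DKO and 110 TPM in WT.

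Of 14541 genes tested, 946 were higher and 614 lower in the libraries labelled DKO, 1560 in all (limma, BH adjusted p under 0.05). Myh7, the slow myosin heavy chain of the fetal and stressed ventricle, had the largest rise among protein-coding genes on the log2(TPM + 1) scale, from 110 ± 109 to 1469 ± 126 TPM, a log2 difference of 4.17 (SE 0.59) and a 13.4-fold ratio. Bex1 (3.04 ± 2.31 to 32.7 ± 4.57 TPM), the metalloproteinase inhibitor Timp1 (2.70 ± 1.89 to 29.3 ± 7.05 TPM), and the matrix genes Cilp (11.2 ± 5.08 to 90.04 ± 2.60 TPM) and Comp (7.45 ± 1.51 to 63.1 ± 10.2 TPM) rose with it, as did Chil1 (0.299 ± 0.259 to 9.08 ± 3.82 TPM). Among the largest falls were the modulatory potassium channel subunit Kcnv2 (11.02 ± 2.33 to 0.784 ± 0.207 TPM) and the clock repressor Ciart (16.0 ± 5.53 to 1.77 ± 1.20 TPM). The abundant mitochondrial creatine kinase Ckmt2 fell from 2153 ± 121 to 396 ± 35.4 TPM, and Coq8a, a kinase-like protein of coenzyme Q biosynthesis, from 307 ± 1.97 to 56.0 ± 7.69 TPM. Penk, Nudt6, Cdnf and Egf also fell, by 2.40, 2.29, 2.25 and 2.12 on the log2 scale; the Penk call was lost without WT 4, WT 5 or DKO 8, with adjusted p (limma, BH) up to 0.0602. Leaving out 1 library moved several of these ratios. Without WT 6, which had 235 TPM of Myh7 against 44.6 and 49.3 in WT 4 and WT 5, the ratio was 31.3 for Myh7 and 17.6 for Timp1 (10.8 with 6 libraries). Without WT 4 it was 19.02 for Bex1 (10.7 with 6 libraries) and 20.3 for Chil1 (30.4). WT over DKO was 14.7 for Ciart without DKO 8 (9.04) and 15.2 for Penk without DKO 9 (7.58).

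Each of the 1560 genes had 3 DKO values entirely above or below the 3 WT values. Among all tested genes this held for 33.0%, against 10% by chance, and 3921 genes had an unadjusted p under 0.05. A TPM ratio of at least 2 was reached by 377 of the higher and 128 of the lower genes. Short RNA rows were among the most extreme differences. Mir6391 (chromosome 14, 118592369 to 118592472, within Abcc4), Mir1962 (chromosome 7, 135566162 to 135566282, within Ptpre), Mir208b (chromosome 14, 54975700 to 54975776, within Myh7) and Snord118 (chromosome 11, 69073426 to 69073562) were listed at 0 in the WT libraries and averaged 53.8, 34.8, 31.2 and 20.4 TPM in DKO. Mir6904 (chromosome 1, 180587201 to 180587267, within Parp1) averaged 32.1 TPM in WT and was listed at 0 in DKO. Reads of a host transcript that cover a short RNA inside it can count toward either row; Ptpre (log2 difference 1.34) and Myh7 were themselves higher, while Abcc4 and Parp1 were not called (limma, BH adjusted p = 0.463 and 0.51). The number of genes called was 834, 803 and 736 without WT replicates 4, 5 and 6, and 815, 622 and 877 without DKO replicates 7, 8 and 9. It was 1, Trim12a, with replicate 7 counted as WT. Over the genes tested, Pearson correlations were at least 0.9512 within DKO, at least 0.9414 within WT and at most 0.9442 between the groups. Replicate 7 was thus closer to DKO 8 and DKO 9 than to any WT library, which argues against its WT tag. Counting it as WT therefore places DKO-like expression in the WT group. Its erythroid mean, 0.173, lay within the WT range (-0.849 to 0.530).

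The libraries differed in sex-linked transcripts. WT 4, 5 and 6 and DKO 9 had Y-linked transcripts, 163 to 179 TPM over Ddx3y, Uty, Kdm5d and Eif2s3y, while DKO 7 and DKO 8 had Xist at 152 and 174 TPM. A term for this difference left 92 genes called, and the 4 libraries with Y-linked transcripts alone gave 12. Xist reached 1 TPM only in DKO 7 and DKO 8, so it did not pass the expression filter and was not tested. None of the 5 tested members of the sex-linked list was called over all genes, and 0 were called when adjusted over the list alone. The mean over the list, relative to WT, was -4.21 and -4.13 in DKO 7 and DKO 8 and 0.0414 in DKO 9. The list was lower in DKO (camera, BH adjusted p = 0.0124; adjusted p = 0.558 with an estimated correlation), and its call was lost without DKO 8 (0.0667). Structural and short RNA took 10.9%, 11.7% and 11.6% of TPM in WT and 14.0%, 12.3% and 12.8% in DKO. Haemoglobin took 0.779%, 3.83% and 1.41% in WT and 0.880%, 0.321% and 0.385% in DKO.

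Ion channel genes changed in both directions. The skeletal muscle sodium channel Scn4a fell from 34.1 ± 1.59 to 9.75 ± 2.31 TPM. The T-type calcium channels Cacna1h (10.8 ± 2.70 to 40.8 ± 9.54 TPM) and Cacna1g (6.12 ± 1.26 to 24.7 ± 9.20 TPM) rose. Of 20 tested sodium, calcium and pacemaker channel genes, 3 were higher and 3 lower, and 4 and 3 when adjusted over the list alone. Among 24 potassium channel genes 3 rose and 5 fell (4 and 6 adjusted over the list alone). Kcne1, the subunit of the slow delayed rectifier, rose from 2.09 ± 1.03 to 18.6 ± 4.81 TPM and Kcna4 from 2.17 ± 0.194 to 13.2 ± 1.74 TPM. Kcnd2, a transient outward channel, fell from 32.2 ± 4.78 to 15.6 ± 1.11 TPM and Abcc9 from 228 ± 5.00 to 143 ± 7.02 TPM. Neither list shifted in 1 shared direction (camera, BH adjusted p = 0.963 and 0.451), a test that does not see changes going both ways.

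Of 22 conduction system markers, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median log2 difference of 0.43 (camera, BH adjusted p = 0.0115; adjusted p = 0.458 with an estimated correlation). The G-protein regulator Rgs6 rose from 10.5 ± 1.09 to 21.6 ± 2.39 TPM and Cacna1g is a member too. The calls of Gjc1 and Id2, also higher, were lost in 5 and 4 of the 6 fits that left out 1 library. The pacemaker channel Hcn4 (6.92 ± 1.06 to 12.6 ± 2.50 TPM) passed with all 6 libraries (limma, BH adjusted p = 0.0401) and in no fit that left 1 out (0.063 to 0.103), nor with quantile scaling (0.0503), without a filter (0.065) or without trend (0.0512). Of 22 intercalated disc and gap junction genes, 5 rose and 1 fell (7 and 5 adjusted over the list alone; camera, BH adjusted p = 0.451). The intercalated disc list passed with replicate 7 as WT (camera, BH adjusted p = 0.0472). Plakophilin Pkp2 rose from 141 ± 1.21 to 212 ± 14.1 TPM and desmoplakin Dsp fell from 623 ± 17.5 to 392 ± 44.5 TPM. Gja1, the main ventricular connexin, was 575 ± 34.2 in WT and 662 ± 67.6 TPM in DKO (limma, BH adjusted p = 0.208).

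Calcium handling and sarcomere genes also divided by member. Skeletal calsequestrin Casq1 rose from 9.40 ± 5.49 to 58.1 ± 7.28 TPM (a ratio of 6.18, and 9.32 without WT 6) and the sodium-calcium exchanger Slc8a1 from 113 ± 4.44 to 170.0 ± 16.0 TPM. The histidine-rich calcium-binding protein Hrc fell from 701 ± 28.0 to 424 ± 11.8 TPM and the release channel Ryr2 from 756 ± 28.6 to 530.4 ± 55.9 TPM. Of 30 calcium handling genes 3 were higher and 2 lower, or 5 and 4 adjusted over the list alone (camera, BH adjusted p = 0.681). The calcium pump Atp2a2 missed the threshold over all genes (limma, BH adjusted p = 0.0574) but passed, as lower, over the list alone (0.026), with a 5 TPM filter (0.0295), with median-ratio scaling (0.0479) and when ribosomal (0.0362) or short RNA (0.0254) was left out. With quantile scaling the log2 difference of Atp2a2 was 0.03 (limma, BH adjusted p = 0.882). Of 31 sarcomere genes, 8 rose and 6 fell (10 and 8 adjusted over the list alone; camera, BH adjusted p = 0.656). Pdlim3 rose from 25.3 ± 7.98 to 78.8 ± 7.20 TPM, Nebl from 155 ± 15.04 to 269 ± 20.8 TPM and Myom1 from 804 ± 26.0 to 1122 ± 34.4 TPM. Troponin Tnni3 fell from 7173 ± 254 to 5077 ± 102 TPM. Ryr2 was not called without WT 4 (limma, BH adjusted p = 0.0538) or WT 5, and Tnni3 not with quantile scaling (limma, BH adjusted p = 0.254).

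In the hypertrophy and fetal gene list 6 of 18 genes were higher and 3 lower (8 and 4 adjusted over the list alone), and the hypertrophy list as a whole did not pass (camera, BH adjusted p = 0.201) except with quantile scaling (0.0425). Beside Myh7 and Cilp, smooth muscle actin Acta2 rose from 66.5 ± 11.1 to 228 ± 63.3 TPM. Skeletal actin Acta1 fell from 682 ± 308 to 164 ± 21.7 TPM. Natriuretic peptide Nppa was 1805 ± 2119 in WT and 3277 ± 944 TPM in DKO and did not pass (limma, BH adjusted p = 0.304). It had 4216 TPM in WT 4 against 242 and 957 TPM in WT 5 and WT 6, and its ratio of 1.82 became 5.47 without WT 4 (limma, BH adjusted p = 0.0551). Nppb did not pass either (limma, BH adjusted p = 0.383). Ventricular markers gave 3 higher and 2 lower of 13 (3 and 4 adjusted over the list alone; camera, BH adjusted p = 0.451). The ventricular list passed, as lower, with fry (fry, BH adjusted p = 0.0367). Atrial markers gave 0 higher and 1 lower, Nr2f2, of 18, and 0 adjusted over the list alone. The atrial list was lower in DKO (camera, BH adjusted p = 0.0044; adjusted p = 0.709 with an estimated correlation), a call lost without WT 4 (0.273), whose mean over the list lay 1.24 above the WT mean against -0.94 and -0.30 in WT 5 and WT 6. Skeletal muscle markers gave 2 higher and 1 lower of 9 (the same numbers adjusted over the list alone; camera, BH adjusted p = 0.451), with Myl1 up from 70.4 ± 14.5 to 173 ± 30.0 TPM.

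Of 40 extracellular matrix genes tested, 24 were higher and 0 lower (30 and 0 adjusted over the list alone), with a median log2 difference of 0.78 (camera, BH adjusted p = 2.87e-14; adjusted p = 0.446 with an estimated correlation). Periostin Postn rose from 36.9 ± 8.82 to 154 ± 8.06 TPM, Col14a1 from 11.5 ± 0.852 to 46.2 ± 13.3 TPM and the crosslinking enzyme Lox from 3.11 ± 0.675 to 13.7 ± 3.07 TPM. Cardiac fibroblast markers gave 6 higher and 0 lower of 16 (7 and 0 adjusted over the list alone; camera, BH adjusted p = 0.00132; adjusted p = 0.558 with an estimated correlation), among them Col3a1 (114 ± 23.8 to 277 ± 50.1 TPM) and Mfap5 (17.5 ± 4.24 to 48.5 ± 7.47 TPM). The calls of Col1a1 and Col1a2, also higher, were lost in 5 and 4 of the 6 fits that left out 1 library.

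**Figure D2:**
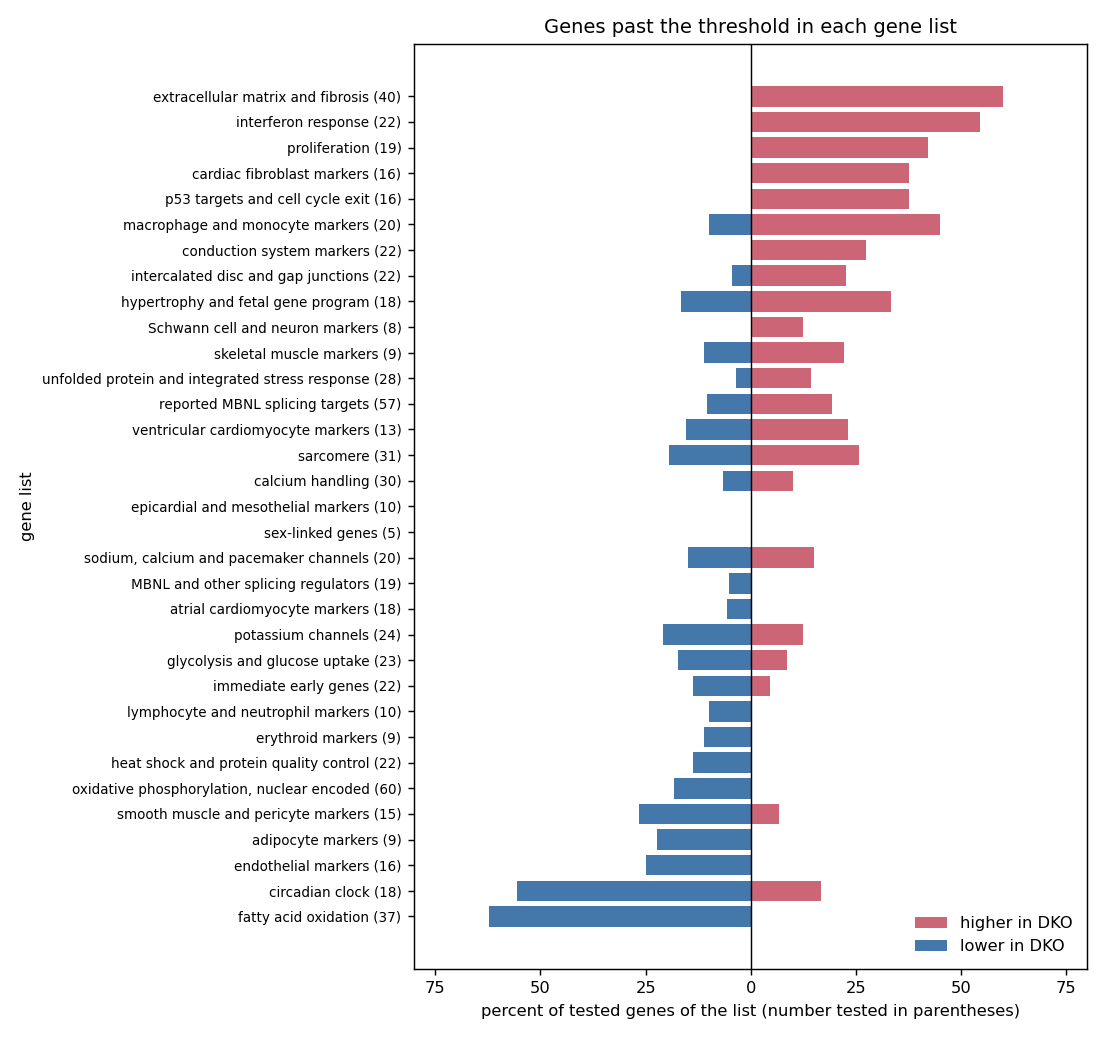
Percent of the tested genes of each gene list that were higher (red, right) or lower (blue, left) in the libraries labelled DKO, with the number tested in parentheses. Of 40 extracellular matrix genes 24 were higher and 0 lower, and of 37 fatty acid oxidation genes 23 were lower and 0 higher.

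Of 37 fatty acid oxidation genes tested, 23 were lower and 0 higher (26 and 1 adjusted over the list alone), with a median log2 difference of -0.53 (camera, BH adjusted p = 4.28e-21; adjusted p = 0.18 with an estimated correlation). The trifunctional protein subunits Hadhb (2336 ± 46.6 to 1064 ± 54.5 TPM) and Hadha (931 ± 24.5 to 528 ± 22.4 TPM) fell, as did the carnitine carrier Slc25a20 (200 ± 9.96 to 112 ± 3.35 TPM) and Decr1 (304 ± 16.4 to 178 ± 4.43 TPM). Nuclear-encoded oxidative phosphorylation genes gave 11 lower and 0 higher of 60, with a median log2 difference of -0.17 (27 and 0 adjusted over the list alone; camera, BH adjusted p = 1.43e-10; adjusted p = 0.446 with an estimated correlation). Cox7a1 among them fell from 4151 ± 367 to 2777 ± 99.2 TPM, a call lost with quantile scaling (limma, BH adjusted p = 0.0741). Of the mitochondrially encoded list 0 genes were tested, and it is not analysed here. Glycolysis and glucose uptake genes gave 2 higher and 4 lower of 23 (4 and 6 adjusted over the list alone; camera, BH adjusted p = 0.379), with the platelet-type phosphofructokinase Pfkp up from 21.2 ± 4.28 to 55.5 ± 2.30 TPM and the insulin-regulated transporter Slc2a4 down from 300.0 ± 11.2 to 195 ± 11.9 TPM.

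Interferon response genes had the largest median log2 difference, 1.11, among called lists that rose and were fixed before the data were examined, with 12 of 22 higher and 0 lower (17 and 0 adjusted over the list alone; camera, BH adjusted p = 5.35e-10; adjusted p = 0.458 with an estimated correlation). Ifit2 rose from 11.4 ± 0.660 to 42.6 ± 2.39 TPM and the transcription factor Irf7 from 7.78 ± 0.727 to 30.7 ± 9.05 TPM. Macrophage and monocyte markers gave 9 higher and 2 lower of 20 (13 and 2 adjusted over the list alone; camera, BH adjusted p = 4.54e-04; adjusted p = 0.458 with an estimated correlation). Complement C1qa rose from 51.0 ± 5.05 to 113 ± 21.6 TPM and Ms4a7 from 3.24 ± 1.26 to 19.2 ± 6.10 TPM. Cd163 and Lyve1, both markers of tissue-resident macrophages, fell from 11.8 ± 0.611 to 4.65 ± 0.147 and from 16.8 ± 1.43 to 8.46 ± 0.742 TPM. Lymphocyte and neutrophil markers gave 0 higher and 1 lower, Cd79a, of 10 (1 and 1 adjusted over the list alone; camera, BH adjusted p = 0.764). With replicate 7 counted as WT the interferon and macrophage lists were not called (camera, BH adjusted p = 0.179 and 0.151).

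Proliferation genes gave 8 higher and 0 lower of 19 (13 and 0 adjusted over the list alone), with a median log2 difference of 0.92 (camera, BH adjusted p = 1.63e-07; adjusted p = 0.18 with an estimated correlation). Mki67 rose from 2.63 ± 0.465 to 7.66 ± 1.46 TPM and Top2a from 2.35 ± 0.375 to 6.51 ± 1.09 TPM. Targets of p53 and genes of cell cycle exit gave 6 higher and 0 lower of 16 (8 and 0 adjusted over the list alone; camera, BH adjusted p = 9.8e-04; adjusted p = 0.289 with an estimated correlation), among them the cyclin-dependent kinase inhibitor Cdkn1a (14.3 ± 4.51 to 67.2 ± 16.1 TPM), Phlda3 (10.9 ± 2.53 to 33.2 ± 1.61 TPM) and Eda2r (4.36 ± 0.766 to 12.9 ± 0.943 TPM). With replicate 7 counted as WT the p53 list was not called (camera, BH adjusted p = 0.0829).

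Unfolded protein and integrated stress response genes gave 4 higher and 1 lower of 28 (5 and 2 adjusted over the list alone; camera, BH adjusted p = 0.95). Gdf15, a secreted stress cytokine, rose from 1.15 ± 0.535 to 12.6 ± 6.06 TPM and the endoplasmic reticulum stress gene Herpud1 fell from 160 ± 7.81 to 94.1 ± 3.44 TPM. Heat shock and protein quality control genes gave 3 lower and 0 higher of 22 (5 and 0 adjusted over the list alone; camera, BH adjusted p = 6.1e-04; adjusted p = 0.458 with an estimated correlation), with the smallest p for the mitochondrial chaperonin Hspd1 (374 ± 9.999 to 297 ± 8.14 TPM). Hspd1 was not called without WT 4 (limma, BH adjusted p = 0.0548), WT 5 or the variance trend (0.063). The other 2, Bag3 and Dnaja1, were called in none of the fits that left out 1 library (limma, BH adjusted p = 0.0503 to 0.0867 and 0.053 to 0.105). Immediate early genes gave 1 higher and 3 lower of 22 (2 and 7 adjusted over the list alone; camera, BH adjusted p = 0.00166; adjusted p = 0.558 with an estimated correlation), with Klf6 down from 52.8 ± 4.61 to 35.5 ± 1.38 TPM. The mean over that list was 0.582 in WT 4, -0.439 and -0.143 in WT 5 and WT 6 and -0.379, -0.416 and -0.655 in DKO 7, 8 and 9. The median log2 difference of the immediate early genes went from -0.50 to -0.32 without WT 4.

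Of 18 circadian clock genes, 10 were lower and 3 higher (12 and 4 adjusted over the list alone; camera, BH adjusted p = 0.00112; adjusted p = 0.446 with an estimated correlation). Per1 fell from 42.0 ± 2.47 to 15.2 ± 4.52 TPM and Tef from 87.6 ± 17.8 to 39.1 ± 7.55 TPM, and Npas2, a partner of Arntl in the activating complex, rose from 3.32 ± 0.626 to 10.7 ± 0.905 TPM.

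Endothelial markers gave 0 higher and 4 lower of 16 (0 and 6 adjusted over the list alone; camera, BH adjusted p = 9.07e-04; adjusted p = 0.458 with an estimated correlation), among them Esam (86.4 ± 6.81 to 56.5 ± 2.42 TPM) and Robo4 (33.6 ± 0.881 to 20.1 ± 2.47 TPM). Of the fits that left out 1 library, the call of Tie1 was lost in 5 and that of Cdh5 in all 6. The mean over the endothelial list overlapped between groups, with WT 5 at -0.129 and DKO 8 at -0.1. Smooth muscle and pericyte markers gave 1 higher and 4 lower of 15 (1 and 8 adjusted over the list alone; camera, BH adjusted p = 5.7e-04; adjusted p = 0.289 with an estimated correlation), where Acta2 rose and Tagln fell from 43.6 ± 6.61 to 24.1 ± 2.66 TPM. Adipocyte markers gave 0 higher and 2 lower of 9, also adjusted over the list alone (camera, BH adjusted p = 0.00825; adjusted p = 0.558 with an estimated correlation), a call lost with the term for sex-linked transcripts (0.49), in Y-linked libraries alone (0.67) and with replicate 7 as WT (0.151). The mean over the adipocyte list, relative to WT, was 0.246, -0.447 and 0.201 in WT 4, 5 and 6 and -0.934, -0.634 and 0.261 in DKO 7, 8 and 9. DKO 9 lay with the WT libraries. Erythroid markers gave 0 higher and 1 lower, Slc4a1, of 9 (1 and 7 adjusted over the list alone; camera, BH adjusted p = 0.00868; adjusted p = 0.522 with an estimated correlation). The mean over that list was -2.41 and -2.08 in DKO 8 and DKO 9, the 2 libraries with Hbb-bs near 1 TPM, but 0.173 in DKO 7 and 0.320, 0.530 and -0.849 in WT 4, 5 and 6. Schwann cell and neuron markers gave 1 higher, Pmp22, and 0 lower of 8 (1 and 0 adjusted over the list alone; camera, BH adjusted p = 0.451), and of 10 epicardial and mesothelial markers 0 passed, also adjusted over the list alone (camera, BH adjusted p = 0.0813). The epicardial list passed, as lower, without the variance trend (camera, BH adjusted p = 0.0497), WT 6 (0.00412) or DKO 7 (0.0412), with replicate 7 as WT (0.0132), with the sex term (0.0291) and in Y-linked libraries alone (0.0489). The calls of Slc4a1 and Pmp22 were each lost in 5 of the 6 fits that left out 1 library, as was that of Cd79a, and Nr2f2 was called in 0 of them. Without the variance trend Pmp22 (limma, BH adjusted p = 0.0621) and Nr2f2 (0.0505, and 0.0642 without a filter) were not called either.

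**Figure D3:**
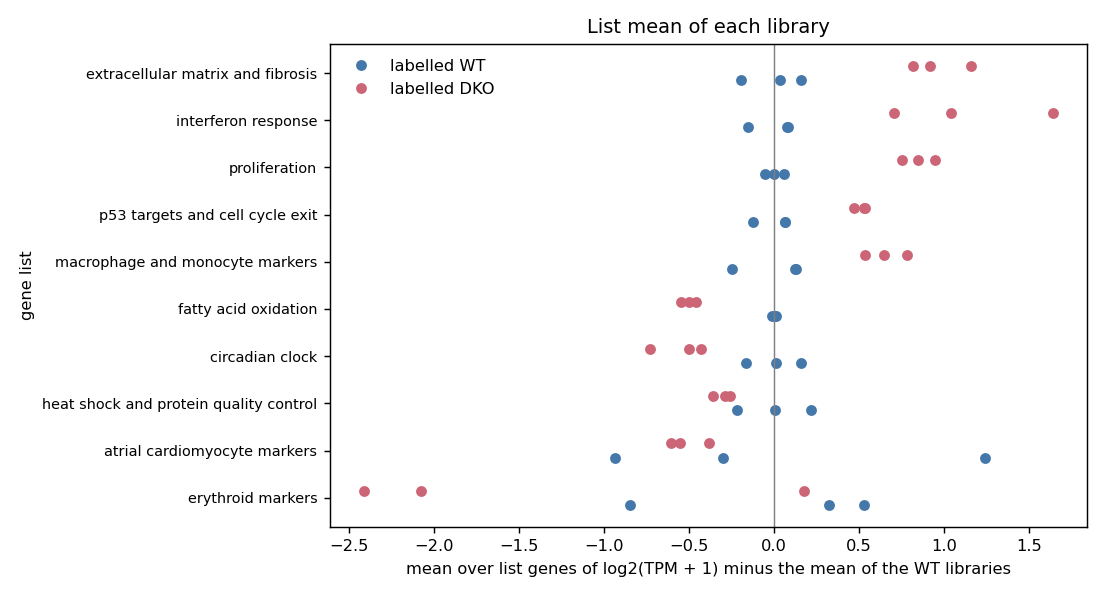
Mean over the tested genes of 10 lists of log2(TPM + 1) minus the mean of the WT libraries, 1 point per library, WT in blue and libraries labelled DKO in red. For fatty acid oxidation the DKO libraries lie between -0.549 and -0.458, and for atrial markers WT 4 lies at 1.24, above the other 5 libraries.

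The splicing lists were measured here only by the total level of each gene. Of 57 tested genes reported as MBNL splicing targets, 11 were higher and 6 lower (13 and 9 adjusted over the list alone). Of all genes tested, 1560 of 14541 were called. The list did not shift in 1 shared direction (camera, BH adjusted p = 0.497), a test that does not see changes going both ways. In the mixed form of fry, which takes rises and falls alike, it passed (fry, BH adjusted p = 1.05e-07). Arhgef7 rose from 74.2 ± 5.61 to 111 ± 2.98 TPM, and Tmem63b (79.1 ± 5.03 to 52.7 ± 1.66 TPM) and the chloride channel Clcn1 (8.64 ± 2.76 to 1.47 ± 0.518 TPM) fell. Troponin Tnnt2 was 7850 ± 294 in WT and 7420 ± 365 TPM in DKO (limma, BH adjusted p = 0.536). In the list of other splicing regulators, which also holds the transcription factors Mef2c and Mef2d, 0 of 19 were higher and 1, Rbfox1, was lower (36.5 ± 1.82 to 18.9 ± 1.34 TPM), also when adjusted over the list alone. That list as a whole did not pass (camera, BH adjusted p = 0.893). It did pass in the mixed form of fry (fry, BH adjusted p = 6.22e-05), so the mixed form does not single out the MBNL targets. Of the 33 lists tested, 18 were called, 7 higher and 11 lower, and 0 with an estimated correlation. The sign of the median differed from that of the mean for the sodium and calcium channel, calcium handling, glycolysis, stress response and ventricular lists.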

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

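The alternatives with a term for sex-linked transcripts, with Y-linked libraries alone, and with rescaling without short RNA were chosen after the results were seen. No paired analysis was possible because the WT libraries are numbered 4 to 6 and the DKO libraries 7 to 9, with no shared number. The planned test of transcript shares was not run, since values are per gene. Depth is unknown, so what it limits was not measured. All 1560 called genes kept their sign under every alternative that tested them. Only scaling and replicate 7 as WT could have turned a sign, since DKO and WT values of each called gene do not overlap. With 1 library left out, 585 to 796 of these genes stayed called in the same direction. Scaling, filter, pseudocount, trend and weights gave 1082 to 2041 called genes. The split of 946 higher and 614 lower became 912 and 826 with median-ratio and 880 and 817 with quantile scaling, nearer to even. The count was 1 with replicate 7 as WT (1439 genes at unadjusted p under 0.05, limma), 92 with the sex term, 12 with Y-linked libraries alone, and 622 to 877 with 1 library left out. The Y-linked fit has 4 libraries, 1 of them DKO, assumed to vary like the others. Mbnl1 was not called with replicate 7 as WT (-0.37; limma, BH adjusted p = 0.529), the sex term (-0.52; 0.0991) or Y-linked libraries alone (-0.52; 0.153). Mbnl2 was not called without trend (0.49; 0.0552), with replicate 7 as WT (0.42; 0.501), with the sex term (0.54; 0.166) or with Y-linked libraries alone (0.54; 0.249), and lay between 0.41 and 0.58 with 1 library left out; the cause was not tested. Of 123 named genes called, 82 stayed called with each library left out in turn and 7 in no such fit. Lists called fell to 0 with an estimated correlation and 9 with fry, and lay between 15 and 19 under the other alternatives. With fry the call was lost for 10 lists (fry, BH adjusted p = 0.0802 to 0.358). They were the heat shock, immediate early, clock, sex-linked, atrial, fibroblast, endothelial, macrophage, adipocyte and erythroid lists.

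Direction turned in 47 cases, 0 of them for a result that was called, and the cause was not tested. With quantile scaling Atp2a2 was 0.0302 and Tnnt2 0.222. Counting replicate 7 as WT gave Tnnt2 0.000955 and Retnlg -0.345. Under the sex term and in Y-linked libraries alone Uty was 0.000492, Kdm5d 0.135, Eif2s3y 0.299 and Nppb -0.0229. With 1 library left out Myl7 ranged from -2.03 to 0.232. The rest are list medians where the test direction turned, which need not turn the sign of the median. Ranges with 1 library left out span every such fit, also those where the direction held. Splicing regulators had 0.0348 without a filter, 0.00614 with median-ratio scaling, 0.0151 without ribosomal RNA and -0.0071 to 0.0983 with 1 library left out. Sodium, calcium and pacemaker channels had -0.00382 with the 5 TPM filter, without trend and with fry, -0.0358 with median-ratio and -0.0222 with quantile scaling, -0.0268 without ribosomal RNA, 0.0464 with weights, 0.0976 with replicate 7 as WT, and -0.0304 to 0.0711 with 1 library left out. The stress response list had -0.0484 without a filter, -0.131 with the 5 TPM filter, -0.0384 with weights, 0.0554 with replicate 7 as WT, -0.0546 with the sex term or Y-linked libraries alone, and -0.103 to 0.14 with 1 library left out. Lymphocyte and neutrophil markers had 0.0621 without a filter, 0.0565 with replicate 7 as WT, 0.118 with the sex term, and 0.0766 to 0.283 with 1 library left out. Calcium handling had -0.0222 with quantile scaling and 0.0297 with replicate 7 as WT, glycolysis 0.0234 with quantile scaling, and the sarcomere 0.0718 in Y-linked libraries alone.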

Other observations

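The tests of sex, splits, harvest time, globin haplotype and chromosome position were chosen or altered after the results were seen. So were the rescaling without short RNA and the 6 gene lists of the next paragraph. The p-values of those lists are therefore not independent tests, and adjustment over 6 lists does not account for the choice.

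Of 77 cytosolic ribosomal protein genes, 58 were higher and 0 lower in the libraries labelled DKO, with a median log2 difference of 0.37 (camera, BH adjusted p = 1.46e-28 over 6 lists; adjusted p = 0.0744 with an estimated correlation). The number was 44 with median-ratio, 53 with quantile scaling and 64 when short RNA was left out, with 0 lower under median-ratio scaling. Rpl3 rose from 192 ± 22.8 to 439 ± 34.1 TPM while its muscle paralog Rpl3l fell from 336 ± 21.1 to 125 ± 12.0 TPM, and reads could be shared between these related genes. Of 11 coenzyme Q genes 6 were lower and 0 higher (camera, BH adjusted p = 2.49e-08; adjusted p = 0.073 with an estimated correlation), with Coq8a, Coq10b (65.9 ± 4.47 to 31.9 ± 4.70 TPM) and Coq10a (162 ± 15.2 to 82.4 ± 1.52 TPM) falling. Of 8 MHC class II genes 5 were higher (camera, BH adjusted p = 1.26e-04; adjusted p = 0.183 with an estimated correlation), among them H2-Aa (70.4 ± 14.3 to 239 ± 118 TPM), with 3 under median-ratio and 4 under quantile scaling and 7 when short RNA was left out. Tubulins gave 7 higher of 15 (camera, BH adjusted p = 5.04e-04; adjusted p = 0.183 with an estimated correlation), with the smallest p for Tuba1b (202 ± 4.91 to 311 ± 38.5 TPM). Of 63 histone genes 9 were higher, or 14 when short RNA was left out, and 0 lower (camera, BH adjusted p = 1.71e-07; adjusted p = 0.073 with an estimated correlation). Of 5 mast cell genes 2 were higher, Cma1 and Tpsb2 (camera, BH adjusted p = 0.0173; adjusted p = 0.183 with an estimated correlation).

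The labelled groups differed at 1560 genes, and sex differs in part with genotype, but against sex as the whole cause DKO 7 and DKO 8, which have Xist, gave 4 called genes (limma) against the other 4 libraries, the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y, and 0 autosomal, with 1720 at unadjusted p under 0.05. At 835 autosomal genes called from DKO 7 and DKO 8 against WT, DKO 9 shifted by 0.824 of their median shift (0.778 to 0.860, 95% over genes) and in the same direction at 99.04%; the same WT libraries served for the calls and the shift, which in 200 simulations of independent noise gave an unchanged library at most 0.44 and 79.3%. A partial contribution of sex stays open, since a sex term leaves DKO 9 as the only DKO library that bears on genotype. With that term Mbnl1 lay at -0.52 and Mbnl2 at 0.54. All 1560 genes kept their sign, which was fixed beforehand, since DKO 9 lay beyond all WT values at each, in the called direction. The fall in called genes with the sex term does not measure sex. Scaling by abundant RNA as the whole cause is argued against by median-ratio, quantile and ribosomal RNA-free scaling, which moved the median log2 difference of all genes from 0.0327 to 0.00336, -0.0242 and 0.0118 and kept 1474, 1418 and 1511 of the 1560 calls; leaving out short RNA and haemoglobin kept 100% of 1552 but moved that median only to 0.0352. The 10 splits of 6 libraries are too few for a share under 0.05; 1 split gave as many genes, the labelled one, and the highest other gave 14.

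Of 8 clock genes that peak with Dbp 7 were lower (median log2 difference -1.24), and of 5 that peak in antiphase 3 were higher (median 0.638, the value of Nfil3, which was not called; limma, BH adjusted p = 0.0791), with Arntl up from 8.09 ± 3.35 to 24.3 ± 4.04 TPM and Dbp down from 142 ± 39.7 to 41.0 ± 18.95 TPM. Dissection of the DKO hearts at another time of day may account for this pattern, which a shift of the clock by genotype would also give; harvest times are not given in the sources used here. Sex as a cause of the clock difference cannot be told apart from genotype here: between Xist libraries and the other 4, 0 clock genes were called (limma) but 11 of 18 had an unadjusted p under 0.05, and only 1 DKO library, DKO 9, has Y-linked transcripts. Against sex, DKO 9 lay outside the WT range at 10 of the 10 clock genes called from DKO 7 and DKO 8. The same WT libraries served for those calls and for that range. The median log2 difference of the circadian clock list was -0.598 with the sex term and in Y-linked libraries alone, against -0.755 in the main fit. These values rest on DKO 9 alone and on genes that vary together. Arntl was not called without WT 6, DKO 7 or DKO 8 (limma, BH adjusted p up to 0.058), nor Dbp without any library but DKO 7 (up to 0.097), without a filter (0.0555) or without trend (0.0573).

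Beta-globin rows switched between libraries. Hbb-b1 and Hbb-b2 made up 50.5%, 0.0866% and 0.0432% of adult beta-globin TPM in WT 4, 5 and 6 and 52.0%, 99.9% and 99.8% in DKO 7, 8 and 9. Different beta-globin haplotypes of the animals are a candidate explanation, since summed beta-globin over alpha-globin in the 2 libraries low in Hbb-bs was 1 times that of the others. Trim12a (chromosome 7, 104299893 to 104315558), on the chromosome that holds the beta-globin genes, was listed at 0 in DKO 8 and DKO 9 and had 12.7, 21.4, 21.6 and 14.9 TPM in WT 4, 5 and 6 and DKO 7. Whether strain background also bears on genes called near the targeted loci cannot be told apart from chance here: within 20 Mb of Mbnl1 or Mbnl2 the share called was 0.996 of that elsewhere (95% interval 0.625 to 1.59; permutation of positions, p = 0.525), an interval too wide to exclude it.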
